A study of Mus musculus with 12 samples.

How the data were processed

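Polyadenylated RNA from mouse colonoids in 4 groups of 3 libraries was analysed from the deposited table of whole-number counts per gene symbol, which the authors made with genome build mm10 per the submitters' processing notes. The aligner, the counter, the counting strand and the annotation are not given in the sources used here, and the counts carry no normalization. Counts of abundant genes levelled off, and some varied less than sampling noise: Rps29, with 693 exon bases, had 177 to 193 counts in all libraries (variance over mean 0.118). The variance over mean was 0.511 for Krt8, but 1.03 for Eef1a1 and 1.17 for Actb. Levelling-off of this kind is the pattern left where reads at the same position are counted once, which the sources do not state. Fold changes of such genes may be compressed, so a value near 0 may hide a change. Raw reads were not used here.

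All 35869 symbols were read, of which 11498 had no count. Genes were kept with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 13987 and removed 21882. Libraries were scaled by TMM (factors 0.957 to 1.04), 1 mean per group was fitted to all 12 libraries with the edgeR quasi-likelihood method (8 residual degrees of freedom), and contrasts were tested for each cytokine treatment against unstimulated, both against each single cytokine, and the interaction. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Gene lists with 5 or more tested genes were compared with all other genes by camera of limma 3.58.1, two-sided, with a preset correlation of 0.01 and with an estimated one as an alternative, adjusted over all lists and comparisons. A call lost in that alternative need not reflect correlated genes. The NF-kB list with IL-22 had an estimated correlation of 0.00977, near the preset, yet its camera adjusted p went from 0.0317 to 0.239. The 25 lists covered STAT3, NF-kB and ER stress genes, antimicrobial and acute-phase proteins, fucosylation and mucin glycosylation, chemokines and cytokines, the IL-1 and IL-22 receptor pathways, interferon-stimulated genes, antigen presentation, stem, goblet, colonocyte, enteroendocrine, tuft and Paneth cell genes, proliferation, tight junctions and surface mucins, wound repair and proteases, cell death and inflammasomes, fibroblast and smooth muscle, endothelial, immune and neural genes, and the dissociation and heat-shock response. The comparisons, tests, lists, alternatives and the rule on named genes were set before the data were examined.

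The rule named the 10 called genes with the largest change in each direction in each comparison against unstimulated, and 5 in each direction for both cytokines against each one. They needed a mean of 1 CPM or more and no overlap between the groups, and clone-type names were passed over. It also named up to 6 called interaction genes per direction, up to 4 called members of each list per comparison (2 where none was called), and a fixed set of 16 cytokine response, receptor, stem cell, goblet cell and proliferation genes. Genes named outside it are said to be chosen after their values were seen.

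Positions are from GENCODE M21 on mm10 (GRCm38): 26762 symbols matched directly and 546 through a RefSeq synonym, and 8561 had no match. Of 213 named genes 212 were placed and 59 share exon bases with another gene model. These include Cxcl10, Stat3, Icam1, Il4ra, Mmp7, Plek, Cdkl1, Prelp, Slc16a9, Timp3, Bcl3, Apoa4, Ereg, Usp18 and Igtp, whose counts are uncertain because the counting strand is not given. The values of some genes are withheld and not reported here. Where a group had 1 to 3 counts a ratio of summed counts is given with its exact 95% counting interval, and where it had none the fold is a bound against a floor of 3 counts over the group. In a single library 3 counts stand for 0.517 to 0.638 CPM. Intervals and floors cover counting error only.

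Alternatives were DESeq2 1.42.0 size factors and its Wald test, total counts as the only scaling, no filter beyond 1 count, a filter at 1 CPM in 6 libraries (which tested 14496 genes), a replicate block, only the 6 libraries compared, and leaving out each library in turn. Further ones were chosen after seeing the data: removal of the trend on count per exon base (lowess, span 0.3), only genes under 0.1 count per exon base, counts corrected for positions counted once, and leaving out unstimulated replicate 1 and IL-1b replicate 1 together. The tests were tried on simulated data of this design with known changes: 8 of 13625 unchanged genes were called for IL-1b and 7 for the interaction. Same-numbered replicates of different groups were not treated as pairs, since their correlations lay between -0.188 and 0.179 and only 2 libraries correlated best with their own number.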

Results

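Polyadenylated RNA was sequenced from colonoids of C57BL/6 mice, which are epithelial structures grown in a basement membrane gel from isolated colonic crypts. Cultures were left unstimulated or received recombinant mouse IL-1b at 100 ng/mL, recombinant mouse IL-22 at 1 ng/mL, or both cytokines for 12 h. IL-1b is an inflammatory cytokine that acts through the IL-1 receptor and NF-kB, and IL-22 is a cytokine of lymphoid cells that acts on epithelium through STAT3. The series asked what IL-1 receptor signalling does within the intestinal epithelium. The 4 groups held 3 libraries each. Library totals lay between 4703902 and 5804033 counts, with means of 5400895 ± 167912 (SD, n = 3) in unstimulated cultures, 5021865 ± 361635 with IL-22, 5462352 ± 298583 with IL-1b and 4989629 ± 279620 with both. Of 35869 gene symbols, 13987 passed the expression filter and were tested. The first principal component held 49.1% of the variance and separated the 6 libraries with IL-22 from the 6 without, and the second component held 10.5%. Over 9220 genes under 0.1 count per exon base, replicates differed by more than sampling noise in every group (chi-square per degree of freedom from 1.69 to 3.58). Each library was counted as 1 sample, though this spread does not show that libraries are independent. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Below, levels are CPM (counts relative to the TMM-scaled library total) with SD, and log2 fold changes carry a standard error, with n = 3 per group. This error is the absolute log2 fold change over the square root of its F statistic, so it is approximate, above all where counts are few. Genes are said to rise or fall where the Benjamini-Hochberg adjusted p of the edgeR quasi-likelihood test was under 0.05.

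IL-22 alone raised acute-phase, antimicrobial and STAT3 feedback genes. Socs3, the feedback inhibitor of STAT3 signalling (mm10 chromosome 11, 117966079 to 117970047), rose from 13.4 ± 5.84 to 209 ± 10.7 CPM, a log2 fold change of 3.95 ± 0.16 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.84e-09). Lbp, the lipopolysaccharide-binding protein (chromosome 2, 158306493 to 158332852), rose by 4.81 ± 0.23, Ltf, which encodes lactoferrin, by 4.20 ± 0.43, the oncostatin M receptor gene Osmr by 5.09 ± 0.51 and the serine protease gene Prss27 by 4.22 ± 0.38. Lrg1, an acute-phase glycoprotein gene (chromosome 17, 56119678 to 56122001), had 3 summed counts in unstimulated cultures and 546 with IL-22, a ratio of 203 (95% counting interval 69.2 to 989). The ratio was 44.0 (14.7 to 216) for Trim10 and 43.2 (14.4 to 213) for Pla2g2a, each against 3 counts. Pla2g2a belongs to the secreted phospholipases, but GENCODE lists it as a polymorphic pseudogene, so its RNA may not yield a working enzyme. Lcn2, which encodes lipocalin 2, went from 2 to 16 summed counts (ratio 8.94, 2.10 to 80.2), a call that was lost without unstimulated replicate 1 or 2 or IL-22 replicate 1. Myl1 and S100a8, a subunit of calprotectin, had no count in the unstimulated libraries and were at least 17.1-fold and at least 12.7-fold higher with IL-22, against a floor of 3 counts over the group. Fut2, which fucosylates epithelial glycans, rose by 1.00 ± 0.05, the oxidase gene Duox2 by 1.81 ± 0.13 and the nitric oxide synthase gene Nos2 by 1.90 ± 0.22. The resistin-like gene Retnlb rose by 3.47 ± 0.59 and the mucin gene Muc1 by 1.94 ± 0.22. Among the genes that fell, the gluconeogenic enzyme gene Pck1 went from 71.5 ± 6.76 to 9.34 ± 3.25 CPM (-2.92 ± 0.21). Cd83 fell by 3.67 ± 0.42, Nxpe2 by 2.70 ± 0.21 and the chloride channel gene Best2 by 2.67 ± 0.38. The epithelial sodium channel subunit gene Scnn1g fell by 2.64 ± 0.63, the monocarboxylate transporter gene Slc16a9 by 2.58 ± 0.26 and the apolipoprotein genes Apoa1 and Apoa4 by 2.84 ± 0.67 and 2.95 ± 0.76. Cdkl1 and Prelp also fell, to 3 summed counts each, with ratios of 0.0578 (0.0116 to 0.178) and 0.0882 (0.0174 to 0.278). Leaving out 1 library moved several values. Without unstimulated replicate 1 the ratio was 401 for Lrg1, 28.9 for Trim10, 28.4 for Pla2g2a and 5.88 for Lcn2, and the bounds of Myl1 and S100a8 were 11.3-fold and 8.33-fold. Without unstimulated replicate 2 it was 135 for Lrg1, 5.94 for Lcn2 and 0.0891 for Cdkl1, Trim10 was at least 29.2-fold higher, and the bounds of Myl1 and S100a8 were 11.4-fold and 8.41-fold. Without unstimulated replicate 3 Pla2g2a had a ratio of 87.9, Lcn2 was at least 4.04-fold higher and Apoa1 stood at -2.09. Without IL-22 replicate 1 Cdkl1 had a ratio of 0.0288, Apoa4 stood at -4.41 and Retnlb at 2.83. Without IL-22 replicate 2 Prelp and Scnn1g had ratios of 0.0425 and 0.0873, and without IL-22 replicate 3 Best2 stood at -3.30 and Apoa1 at -2.24.

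The chemokine genes went both ways with IL-22. Cxcl5 and Cxcl1, which attract neutrophils, rose by 2.50 ± 0.39 and 1.63 ± 0.31, whereas Ccl20, the ligand of CCR6, fell by 1.79 ± 0.26. The CXCR3 ligand gene Cxcl10 fell by 1.41 ± 0.31 and Cxcl11 by 1.63 ± 0.45. GENCODE lists Cxcl11 as a polymorphic pseudogene, so its RNA may not yield a working protein. Cxcl11 lost its call without unstimulated replicate 3 (adjusted p = 0.0579) or IL-22 replicate 1 (0.0520) or 3 (0.0622). Of 22 chemokine and cytokine genes tested, 6 rose and 4 fell (6 and 5 adjusted over the list alone), and camera, a competitive gene set test, made no call (adjusted p = 0.857, with a median and a mean of -0.03 against a test in the other direction). Of 24 antimicrobial and acute-phase genes, 15 rose and none fell (19 adjusted over the list alone; camera adjusted p = 1.82e-17). Of 19 STAT3 target and feedback genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 1.49e-12), among them Il4ra (1.23 ± 0.07), Pim3 (1.18 ± 0.06) and Stat3 itself (0.59 ± 0.07). Of 26 ER stress genes, 18 rose and none fell (19 and 1 adjusted over the list alone; camera adjusted p = 1.50e-14), among them Chac1 (1.02 ± 0.10), the transcription factor gene Xbp1 (0.62 ± 0.05), Asns (0.58 ± 0.06) and Hyou1 (0.57 ± 0.07). Of 25 fucosylation and mucin glycosylation genes, 13 rose and 2 fell (17 and 3 adjusted over the list alone; camera adjusted p = 6.57e-07, and adjusted p = 0.162 with an estimated correlation). B3gnt5 rose by 0.72 ± 0.13, and the sialyltransferase gene St6gal1 (-0.88 ± 0.17) and Fut4 (-0.65 ± 0.16) fell. Of 28 NF-kB target and feedback genes, 11 rose and 4 fell (12 and 4 adjusted over the list alone; camera adjusted p = 0.0317, and 0.239 with an estimated correlation), including the adhesion gene Icam1 (2.36 ± 0.44), Rel (0.86 ± 0.17), Bcl3 (0.69 ± 0.07) and Nfkbia (0.47 ± 0.08).

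Epithelial lineage and barrier genes changed as well. Of 25 goblet cell genes, 9 fell and 2 rose (11 and 2 adjusted over the list alone; camera, lower, adjusted p = 0.0150, and 0.432 with an estimated correlation). The goblet cell genes Ano7, Capn9 and Ern2 fell by 0.81 ± 0.14, 0.76 ± 0.13 and 0.72 ± 0.12, while the mucin gene Muc2 stood at -0.02 ± 0.08 and did not pass the test. Of 20 wound repair and protease genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.000544, and 0.427 with an estimated correlation). The EGF receptor ligand gene Ereg stood at 1.04 ± 0.25, the plasminogen activator gene Plat at 1.26 ± 0.27 and Timp3, the member that fell, at -1.73 ± 0.44. Of 30 cell death and inflammasome genes, 12 rose and 4 fell (13 and 5 adjusted over the list alone; camera adjusted p = 0.00140, and 0.295 with an estimated correlation). Those that rose held the necroptosis genes Zbp1 (2.14 ± 0.34), Ripk3 (1.02 ± 0.07) and Mlkl (0.79 ± 0.07). Of 24 tight junction and surface mucin genes, 11 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 0.000234, and 0.380 with an estimated correlation), among them Cldn2 (0.89 ± 0.19) and Cldn8 (0.59 ± 0.10), with Cldn15 lower (-0.53 ± 0.12). Of 35 colonocyte genes, 11 rose and 4 fell (14 and 6 adjusted over the list alone; camera adjusted p = 0.0139, and 0.558 with an estimated correlation). The brush-border phosphatase gene Alpi was among those that fell (-0.92 ± 0.20). Of 18 intestinal stem cell genes, 4 rose and 2 fell with the same counts adjusted over the list alone (camera adjusted p = 0.648), with Ephb3 higher (0.97 ± 0.18) and Sox9 lower (-0.65 ± 0.16), though not without IL-22 replicate 2 (adjusted p = 0.0509). Lgr5 (0.28 ± 0.62) and the proliferation gene Mki67 (0.30 ± 0.14) did not pass the test, though Mki67 did without IL-22 replicate 3 (0.45, adjusted p = 0.0270).

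In all, 3144 genes changed with IL-22 (1661 higher and 1483 lower; 251 and 332 of them by at least 2-fold). Fold changes followed the count per exon base in the libraries with IL-22: the median log2 fold change was -0.18 for the 3198 genes under 0.02 counts per base and 0.13 for the 445 genes at 0.4 or more, against -0.01 in both classes with IL-1b alone. With that trend removed, 2784 genes were called, 288 higher and 228 lower by at least 2-fold, and the colonocyte and tight junction calls ended (camera adjusted p = 0.918 and 0.0547). The colonocyte call was also lost without unstimulated replicate 1 (adjusted p = 0.0630). Scaling by total counts alone gave 1206 higher and 1991 lower (37.7% higher, against 52.8%), and without unstimulated replicate 2 the count was 1992. The call of Apoa4 was lost without unstimulated replicate 3 (-2.19, adjusted p = 0.0545) or IL-22 replicate 2 (-2.70, adjusted p = 0.0606).

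**Figure D1:**
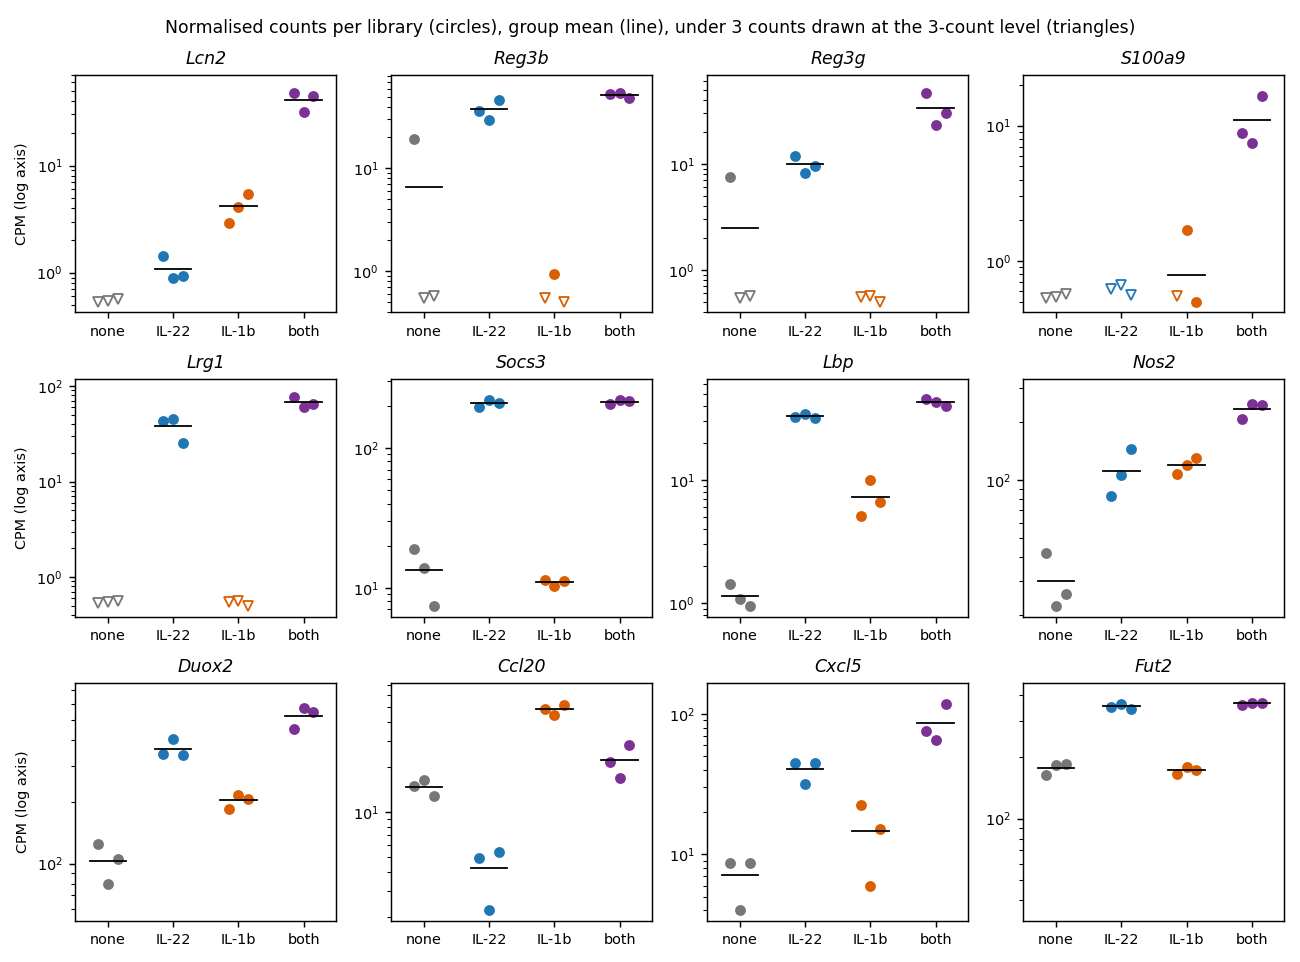
TMM-scaled CPM of 12 genes on log axes, in libraries from unstimulated, IL-22, IL-1b and combined cultures; circles are libraries, lines are the means of groups with 10 or more counts, and triangles mark libraries under 3 counts at the level of 3 counts. Lcn2 went from 0.126 CPM in unstimulated to 41.1 CPM in combined cultures, while Ccl20 was lowest with IL-22 (4.21 CPM) and highest with IL-1b (48.5 CPM).

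IL-1b alone changed few genes at this depth, and the 10 that passed the quasi-likelihood test rose, whereas other settings also called lower genes. The 10 encode antimicrobial, complement, oxidase, chemokine and cytokine products, among others. Lcn2 (chromosome 2, 32384633 to 32388252), whose product binds siderophores, had 2 summed counts in unstimulated cultures and 71 with IL-1b, a ratio of 34.7 (9.25 to 292). The ratio was 22.8 (6.08 to 192) without unstimulated replicate 1, its counting interval was 6.15 to 194 without replicate 2, and Lcn2 was at least 15.7-fold higher without replicate 3. Lbp rose by 2.62 ± 0.29, the nitric oxide synthase gene Nos2 (chromosome 11, 78920787 to 78960254) by 2.00 ± 0.21, Ccl20 (chromosome 1, 83116766 to 83119167) by 1.71 ± 0.19 and the complement gene C3 by 1.57 ± 0.20 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p from 0.00143 to 0.00324 for these 4). Duox2 and its maturation factor gene Duoxa2 rose by 0.98 ± 0.13 and 1.24 ± 0.16, the neutrophil surface protein gene Cd177 by 1.22 ± 0.15, Tnf by 0.91 ± 0.15 and the chloride channel accessory gene Clca4b by 0.78 ± 0.12. Duoxa2 shares exon bases with Duoxa1, so its count is uncertain. Of the same 24 antimicrobial and acute-phase genes, 6 rose (7 adjusted over the list alone; camera adjusted p = 3.67e-17). Of 22 chemokine and cytokine genes, 2 rose (6 adjusted over the list alone; camera adjusted p = 4.49e-15). Of 28 NF-kB target and feedback genes none passed over all genes by the quasi-likelihood test and 8 were higher adjusted over the list alone (camera adjusted p = 2.24e-06). Among these, Zc3h12a stood at 0.57 ± 0.10 and Birc3 at 0.36 ± 0.08, and DESeq2 called both and Casp4. Casp4 also passed without IL-1b replicate 2, and Nfkbiz, which was named after its values were seen, without unstimulated replicate 1. Zc3h12a also passed without unstimulated replicate 1 (adjusted p = 0.0330) and with total counts (0.0402), and Birc3 without unstimulated replicate 3 (0.0222). Of 38 interferon-stimulated genes none passed over all genes by that test, except Ifit3 (also named after its values were seen) without IL-1b replicate 3, and 11 were higher adjusted over the list alone (camera adjusted p = 5.58e-11, and 0.308 with an estimated correlation), with Gbp6 at 2.16 ± 0.47. Cxcl1 (1.43 ± 0.31), Il1r1 (-0.53 ± 0.31), Socs3 (-0.30 ± 0.23) and Fut2 (-0.03 ± 0.06) did not pass the test, although DESeq2 called Cxcl1. The proliferation and heat-shock lists were lower by camera (adjusted p = 0.0143 and 0.0458, and 0.837 and 0.432 with an estimated correlation), with no gene called in either by the quasi-likelihood test or DESeq2. Each list call was lost without 1 library: proliferation had an adjusted p of 0.354 without IL-1b replicate 1, and the heat-shock list 0.124 without unstimulated replicate 1.

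The quasi-likelihood test called 10 genes higher and none lower, with 1338 genes at an unadjusted p under 0.05 and 699 expected by chance, and DESeq2 called 32, 22 higher and 10 lower. Leaving out unstimulated replicate 3 gave 28 calls, 12 higher and 16 lower, and no filter gave 156 higher and 56 lower. Tnf and Clca4b each lost their call without IL-1b replicate 1, 2 or 3, with adjusted p of 0.0928 to 0.109 for Tnf and 0.0844 to 0.101 for Clca4b. Tnf also lost it without unstimulated replicate 1 or 2 (adjusted p = 0.179 and 0.217) and with the trend on count per exon base removed (0.0536). A replicate block left 8 calls, without Tnf (adjusted p = 0.0711) and Clca4b (0.0520). In simulated data of this design the test called 63.6% of genes changed 1.5-fold and 89.6% of those changed 2-fold. Each simulated gene had the spread typical of its level and many changes were planted, so the real shares may be lower. Leukocyte transcripts stood out in IL-1b replicate 1: Ptprc had 104 counts there, 20 and 12 in the other IL-1b libraries and at most 2 in unstimulated ones. The 7 immune genes tested were higher by camera (adjusted p = 0.000368, and 0.0855 with an estimated correlation), with none called over all genes by the quasi-likelihood test and 3 higher adjusted over the list alone. DESeq2 called Ptprc and Laptm5, and Ptprc also passed without IL-1b replicate 3.

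Both cytokines together gave the most calls against unstimulated cultures. Of the 1661 genes called higher with IL-22 alone, 1315 were also called higher with both. The 10 genes called higher with IL-1b alone were too, though Ccl20 and Cd177 rose by less than with IL-1b alone. Lcn2 reached 41.1 ± 8.50 CPM, from 0.126 ± 0.219 in unstimulated, 1.09 ± 0.308 with IL-22 and 4.19 ± 1.27 with IL-1b, a ratio of 335 (92.3 to 2773) over unstimulated. Lrg1 had 1002 summed counts against 3 (ratio 372, 127 to 1806), S100a9 160 against 1 (ratio 178, 31.5 to 7078), Trim10 186 against 3 (ratio 69.0, 23.3 to 338) and Pla2g2a 112 against 3 (ratio 41.6, 13.9 to 205). Myl1 and S100a8 were at least 33.0-fold and 25.6-fold higher, against the floor of 3 counts. Lbp rose by 5.19 ± 0.23, Ltf by 5.07 ± 0.40, Socs3 by 3.98 ± 0.16, the matrix metalloproteinase gene Mmp7 by 3.90 ± 0.48, Nos2 by 2.97 ± 0.21, Duox2 by 2.35 ± 0.13 and Fut2 by 1.04 ± 0.05. The neutrophil-attracting chemokine genes Cxcl2, Cxcl5 and Cxcl1 rose by 3.71 ± 0.60, 3.58 ± 0.36 and 2.40 ± 0.29, and Ccl20 by 0.59 ± 0.20. Best2 fell by 4.22 ± 0.47, Nov by 3.72 ± 0.32, Apoa4 by 3.70 ± 0.84, the ganglioside synthase gene St3gal5 by 3.58 ± 0.64, Rassf10 by 3.46 ± 0.59, Cd83 by 3.46 ± 0.40 and the IL-1 receptor gene Il1r1 by 1.13 ± 0.33. Cdkl1 (1 count against 58, ratio 0.0192, 0.000478 to 0.111), the cytochrome P450 gene Cyp2w1 (3 against 139, ratio 0.0240, 0.00489 to 0.0717) and Hoxd12 (3 against 40, ratio 0.0835, 0.0165 to 0.262) fell to almost no counts. Without unstimulated replicate 1 the ratio was 733 for Lrg1, 220 for Lcn2, 45.4 for Trim10, 27.3 for Pla2g2a and 0.0372 for Cyp2w1, S100a9 was at least 39.0-fold higher, and the bounds of Myl1 and S100a8 were 21.7-fold and 16.8-fold. Without unstimulated replicate 2 it was 247 for Lrg1, 223 for Lcn2, 118 for S100a9 and 0.0296 for Cdkl1, Trim10 was at least 45.9-fold higher, and the bounds of Myl1 and S100a8 were 21.9-fold and 17.0-fold. Without unstimulated replicate 3 Lcn2 was at least 151-fold higher, Pla2g2a had a ratio of 84.5 and Apoa4 stood at -2.94. Without combined replicate 1 Cdkl1 was at least 11.5-fold lower and Hoxd12 had a ratio of 0.126. Without combined replicate 2 Cdkl1 and Cyp2w1 had ratios of 0.0294 and 0.0368 and Hoxd12 was at least 7.83-fold lower, and without combined replicate 3 Cyp2w1 and Apoa4 had ratios of 0.0117 and 0.0328.

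Of the 24 antimicrobial and acute-phase genes, 19 rose with both cytokines (20 adjusted over the list alone; camera adjusted p = 3.17e-26). The STAT3 list had 10 genes higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 1.57e-12). The ER stress list had 19 higher and 1 lower (21 and 1 adjusted over the list alone; camera adjusted p = 3.63e-13). The NF-kB list had 15 higher and 3 lower (18 and 5 adjusted over the list alone; camera adjusted p = 0.000153). The chemokine list had 10 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.0107, and 0.351 with an estimated correlation). Its lower members were Cxcl9 (-1.60 ± 0.53), Cxcl10 (-1.89 ± 0.32) and Cxcl11 (-2.61 ± 0.52), and Ccl28, which was named after its values were seen. Cxcl9 lost its call with DESeq2 (adjusted p = 0.0933), with the trend on count per exon base removed (0.0973), and without unstimulated replicate 1 (0.0829) or 3 (0.143) or combined replicate 2 (0.113) or 3 (0.121). The goblet cell list had 8 lower and 2 higher (9 and 2 adjusted over the list alone; camera adjusted p = 0.00142, and 0.351 with an estimated correlation). Ramp1 stood at -1.18 ± 0.15 and Creb3l1 at -1.05 ± 0.12, and Retnlb rose by 3.35 ± 0.59. Fucosylation (13 higher, 3 lower), wound repair (12 and 1), cell death (13 and 5), tight junction (9 and 1) and colonocyte genes (12 and 5) had camera adjusted p of 0.000226, 0.000234, 0.00340, 0.00426 and 0.0422, which were 0.308, 0.406, 0.308, 0.463 and 0.666 with an estimated correlation. Adjusted over each list alone these had 16 and 4, 14 and 2, 14 and 6, 10 and 1, and 13 and 6 genes higher and lower. In all, 3783 genes changed (1920 higher and 1863 lower; 326 and 503 by at least 2-fold). With the trend on count per exon base removed the 2-fold counts were 376 and 357, and the tight junction and colonocyte calls ended (adjusted p = 0.232 and 0.840). Total-count scaling gave 39.8% of calls higher, against 50.8%, and the calls of Ccl20 and Il1r1 were each lost without unstimulated replicate 1 (adjusted p = 0.0919 and 0.0851) or 2 (0.0602 and 0.0572). Il1r1 also lost its call without combined replicate 2 (adjusted p = 0.0758), and Ccl20 without unstimulated replicate 3 (0.118) or combined replicate 1 (0.0815) or 3 (0.207). Trend removal ended both calls (adjusted p = 0.0508 for Il1r1 and 0.0546 for Ccl20), and Ccl20 also lost its call with total counts (0.0652) and with a replicate block (0.0514). Without unstimulated replicate 1 the colonocyte list had an adjusted p of 0.134. The dissociation and heat-shock list had 9 higher and 1 lower of 17 (10 and 3 adjusted over the list alone; camera adjusted p = 0.0382, 0.427 with an estimated correlation and 0.104 with the trend removed). Of the lists for other cell types, immune genes had 3 higher and 1 lower of 7 (camera adjusted p = 0.0552, 0.351 with an estimated correlation, 0.0347 with total counts, 0.0279 with the trend removed and 0.0416 without IL-1b replicate 1), and fibroblast and smooth muscle genes 1 higher and 1 lower of 6 (camera adjusted p = 0.574). Endothelial genes had 2 of 4 lower and neural genes 1 of 2 lower, lists too small for camera, and the counts of the 4 lists adjusted over the list alone were the same. Of these calls, the endothelial genes Vwf and Pecam1 and the neural gene Uchl1 lost theirs in some runs that left out 1 library. Vwf did without unstimulated replicate 1 (adjusted p = 0.0950) or 3 (0.0845) or combined replicate 2 (0.0715) or 3 (0.132), with DESeq2 (0.133) and with the trend removed. Pecam1 did without combined replicate 1 (0.0570) or 3 (0.0549) and stood at -2.38 without combined replicate 2, and Uchl1 lost its call without unstimulated replicate 2 (0.0591). The immune gene Ms4a1 lost its call without unstimulated replicate 1 (0.0645) or 3 (0.0517) or combined replicate 2 (0.0511) or 3 (0.0534). Without unstimulated replicate 2 it had 2 control counts and a ratio of 11.8 (3.02 to 102).

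**Figure D2:**
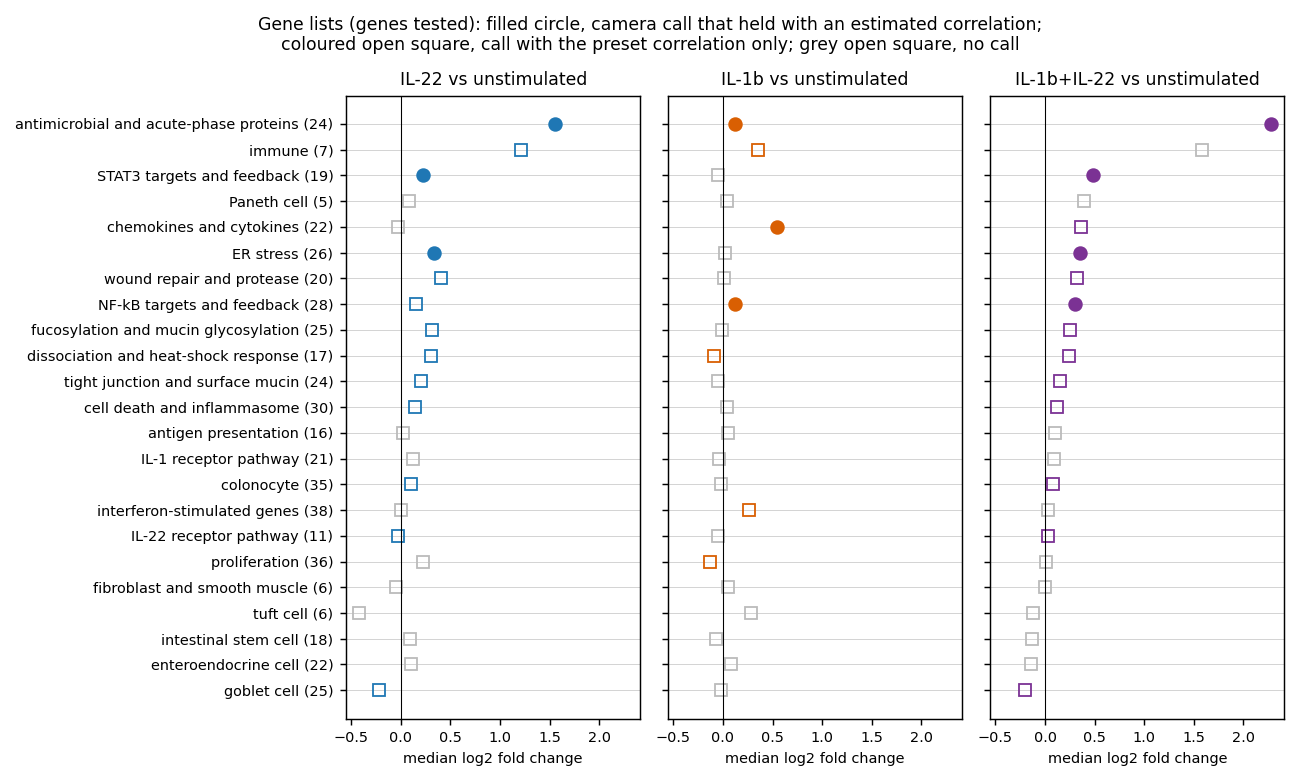
Median log2 fold change of the tested members of 23 gene lists against unstimulated cultures, with the number of genes tested in brackets; filled circles are camera calls that held with an estimated correlation, coloured open squares calls with the preset correlation only, and grey squares no call. The antimicrobial and acute-phase list was called in all 3 comparisons, and the STAT3 and ER stress lists in those with IL-22.

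The Reg3 lectin genes, which encode secreted antimicrobial proteins, depended on 1 control library. Reg3b (chromosome 6, 78370657 to 78373466) stood at 6.54 ± 11.2 CPM in unstimulated, 37.8 ± 8.60 with IL-22, 0.430 ± 0.442 with IL-1b and 52.0 ± 3.27 with both. Reg3g (chromosome 6, 78466269 to 78468872) stood at 2.50 ± 4.32, 9.93 ± 1.91, 0.236 ± 0.206 and 33.3 ± 11.9 CPM in the same order. Unstimulated replicate 1 held 109 Reg3b and 42 Reg3g counts, and the other unstimulated libraries held 1 and 0 of Reg3b and none of Reg3g. Reg3b rose with IL-22 by 2.51 ± 0.67 and with both by 2.96 ± 0.66. Reg3g rose with both by 3.70 ± 0.66, whereas its 1.95 ± 0.74 with IL-22 did not pass the test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0720). With a replicate block Reg3g stood at 2.16 with IL-22 and passed (adjusted p = 0.0382). Without unstimulated replicate 1, which left 1 Reg3b count and no Reg3g count in the controls, both genes passed with IL-22 (adjusted p = 4.93e-07 and 0.000150). The Reg3b ratio of summed counts was then 412 (73.7 to 16309) with IL-22 and 561 (100 to 22199) with both, and Reg3g was at least 35.8-fold and at least 120-fold higher. Without unstimulated replicate 2 Reg3b stood at 1.93 (adjusted p = 0.0511), and DESeq2 with all libraries called neither gene in either comparison. Against IL-1b alone, both cytokines raised Reg3g by 6.99 ± 0.97 and Reg3b by 6.88 ± 1.05, and without IL-1b replicate 2 the Reg3b ratio was 298 (82.3 to 2469), against 125 with all libraries. These genes are close paralogs, and reads shared between them could have been split in counting.

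Adding IL-1b to IL-22 raised 9 genes and lowered 2 relative to IL-22 alone by the quasi-likelihood test, a balance that turned in other settings. S100a9 and Lcn2 rose the most, by 5.21 ± 0.65 and 5.20 ± 0.32, followed by Mmp7 (2.53 ± 0.41) and Ccl20 (2.38 ± 0.25). The others were the prolactin family gene Prl2a1 (1.78 ± 0.28), Clca3a1 (1.77 ± 0.28), C3 (1.25 ± 0.17), Clca3b (1.12 ± 0.18) and Nos2 (1.07 ± 0.18). The genes that fell were 9130208D14Rik (-0.98 ± 0.15) and Cyp2d13 (-0.44 ± 0.07), whose change was small. Clca3a1 and 9130208D14Rik fall outside the rule on named genes and were named after their values were seen. Antimicrobial genes were higher as a list (4 called, 11 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.61e-13). So were chemokines (1 called, 7 higher adjusted over the list alone; camera adjusted p = 2.51e-09) and NF-kB genes (none called by the quasi-likelihood test, Zc3h12a and Tnfaip2 by DESeq2, 4 higher adjusted over the list alone; camera adjusted p = 7.23e-05). Proliferation, enteroendocrine and goblet cell genes were lower as lists with no member called by the quasi-likelihood test (camera adjusted p = 0.000187, 0.000308 and 0.0403, and 0.704, 0.375 and 0.501 with an estimated correlation), 1 goblet cell gene being lower adjusted over the list alone. DESeq2 called the goblet cell gene Creb3l1. The test called 11 genes (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), with 1440 at an unadjusted p under 0.05, and DESeq2 called 87 (27 higher and 60 lower), among them 10 of the 11 but not S100a9. No filter gave 120 higher and 216 lower. Lcn2, Ccl20 and S100a9 kept their calls whichever library was left out, and the other 8 each lost theirs in some such run. S100a9 stood at 4.61 without IL-22 replicate 3. C3 lost its call without IL-22 replicate 3 (adjusted p = 0.0627) or combined replicate 2 (0.0557) or 3 (0.0586). Mmp7 lost it without IL-22 replicate 2 (0.217) or 3 (0.117) or combined replicate 1 (0.0717) or 3 (0.165). Nos2 lost it without IL-22 replicate 2 (0.217) or combined replicate 2 (0.118) or 3 (0.192), with the trend removed (0.0731), with a replicate block (0.0731) and with DESeq2 size factors (0.0526). A replicate block also ended the calls of Clca3a1, Prl2a1 (0.0731) and Cyp2d13 (0.0909). Prl2a1, Clca3b and Cyp2d13 each lost theirs without IL-22 replicate 2 (0.193, 0.216 and 0.193) or 3 (0.0980, 0.0651 and 0.0627) or combined replicate 2 (0.110, 0.0760 and 0.115) or 3 (0.165, 0.165 and 0.196), and Cyp2d13 also without combined replicate 1 (0.0542). There were 3 calls without combined replicate 3, 4 without IL-22 replicate 3 or combined replicate 2, 5 without IL-22 replicate 2, 28 without combined replicate 1 (14 higher and 14 lower) and 72 without IL-22 replicate 1 (20 higher and 52 lower).

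Adding IL-22 to IL-1b changed 3682 genes relative to IL-1b alone (1860 higher and 1822 lower; 289 and 461 by at least 2-fold). Lrg1 had 1002 counts against 1 (ratio 1142, 204 to 45137), Trim10 186 against 2 (ratio 106, 28.9 to 881) and Myl1 89 against 2 (ratio 50.7, 13.6 to 425), Socs3 rose by 4.28 ± 0.16 and Lcn2 by 3.27 ± 0.25. Ccl20 fell by 1.12 ± 0.18, Best2 by 4.10 ± 0.47, Cd83 by 3.82 ± 0.39, Plek by 3.37 ± 0.44 and Slc16a9 by 3.36 ± 0.28, and Cdkl1 had 1 count against 103 (ratio 0.0111, 0.000277 to 0.0630). Without combined replicate 1 Slc16a9 stood at -3.99 and Cdkl1 was at least 20.0-fold lower, and without combined replicate 2 the ratio was 0.0169 for Cdkl1 and 0.0601 for Usp18. Without IL-1b replicate 2 Lrg1 was at least 260-fold higher, and without IL-1b replicate 3 the ratio was 732 for Lrg1 and 32.5 for Myl1. Interferon-stimulated genes were lower: 11 of 38 fell and 3 rose (13 and 3 adjusted over the list alone; camera adjusted p = 0.0257, and 0.738 with an estimated correlation). Usp18 stood at -3.03 ± 0.71, Cxcl9 at -2.50 ± 0.47, Cxcl10 at -2.22 ± 0.32 and Igtp at -2.01 ± 0.28. The list call was lost without IL-1b replicate 1, the library with leukocyte transcripts (adjusted p = 0.240), and after removal of the trend on count per exon base (adjusted p = 0.0695). Of the 7 immune genes 3 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.770). Those that fell included Ptprc (-2.81 ± 0.81) and Laptm5 (-2.02 ± 0.66), and both lost their calls without IL-1b replicate 1 (-1.29, adjusted p = 0.151, and -0.92, adjusted p = 0.284), without combined replicate 1 (adjusted p = 0.0690 and 0.115) and with the trend removed (0.0535 and 0.0737). Ptprc also lost it without combined replicate 3 (0.0515), and Laptm5 without combined replicate 2 (0.0879) and with a replicate block (0.0782), and without combined replicate 3 Laptm5 stood at -2.84. The antimicrobial list had 16 genes higher (18 and 1 lower adjusted over the list alone; camera adjusted p = 1.33e-14). The STAT3 list had 11 higher and 1 lower (12 and 1 adjusted over the list alone; camera adjusted p = 1.50e-14). The ER stress list had 20 higher (22 and 1 lower adjusted over the list alone; camera adjusted p = 8.72e-13). The dissociation and heat-shock list, set as a check on RNA and culture quality, was higher too, with 11 higher and 2 lower of 17 (12 and 2 adjusted over the list alone; camera adjusted p = 0.00142, and 0.308 with an estimated correlation). It shares Atf3 with the ER stress list, and whether its rise reflects quality was not tested. Trend removal moved the 2-fold counts to 346 higher and 304 lower, and total-count scaling gave 36.8% of calls higher, against 50.5%.

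The crossed design also tests whether the log2 responses to the cytokines add up. No gene had an interaction by the edgeR quasi-likelihood test, with 705 genes at an unadjusted p under 0.05 and 699 expected by chance. DESeq2 called 4 genes, Lbp, Clca4b, Adh6a and Sgk1, of which Adh6a and Sgk1 were named after their values were seen. Lbp came closest, with a log2 interaction of -2.24 ± 0.33 (Benjamini-Hochberg adjusted p = 0.124): its change by IL-1b was 2.62 ± 0.29 without IL-22 and 0.38 ± 0.14 in its presence. It was the 1 gene called without IL-1b replicate 1. Nos2 (-0.93 ± 0.28), Duox2 (-0.45 ± 0.18) and Ccl20 (0.67 ± 0.32) did not pass. Lcn2 did not pass either, at 0.34. Unstimulated cultures held 2 Lcn2 counts, too few to rely on its derived standard error (3.37). In simulated data the interaction test called 52.2% of genes with a 1.5-fold and 74.2% of those with a 2-fold interaction. The real shares may be lower here too, since Lbp did not pass at -2.24. As lists, interferon-stimulated, enteroendocrine, immune and antimicrobial genes had lower interactions by camera (adjusted p = 3.92e-11, 4.28e-05, 0.000688 and 0.00317, and 0.308, 0.330, 0.106 and 0.344 with an estimated correlation). The antimicrobial list had a median of -0.12 but a mean of 0.23, with 1 gene higher and 4 lower adjusted over the list alone.

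Responses were compared between settings. The IL-22 effect without and with IL-1b, which share no library, had Pearson r = 0.80 and Spearman rho = 0.73 across the 13987 genes, which are not independent replicates. Of the 3144 genes called for IL-22 alone, 3099 (98.6%) had the same sign with IL-1b present, at a slope of 0.92, and 1257 higher and 1018 lower calls were shared, against 221 and 193 for independent lists. The IL-1b effect without and with IL-22 had r = 0.29 and rho = 0.27 and shared 4 calls, C3, Ccl20, Lcn2 and Nos2, against 0.00643 for independent lists. With DESeq2 they shared 9 higher and 1 lower, and 3 (without Nos2) with DESeq2 size factors, a replicate block or the trend removed. All 17 genes called for IL-1b with or without IL-22 were called with both cytokines against unstimulated, and 12 of them with IL-22 alone. The 12 include Ccl20, which fell with IL-22 (-1.79 ± 0.26) and rose with IL-1b (1.71 ± 0.19). IL-22 and IL-1b, compared with the same 3 unstimulated libraries, shared 8 higher calls (C3, Clca4b, Duox2, Duoxa2, Lbp, Lcn2, Nos2 and Tnf) and no lower one, against 1.19 for independent lists. With DESeq2 they shared 14 higher and 8 lower calls, against 2.36 and 0.781 for independent lists. In 20 simulations of unchanged groups 0 calls were shared, but unchanged groups leave few calls to share, so this sets no benchmark. The log2 fold changes of IL-22 and IL-1b had r = 0.24 and rho = 0.18 (simulated r = 0.49) and a covariance of 0.0325 (simulated 0.0180). The controls were too few to split, so part of the overlap may come from shared controls.

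**Figure D3:**
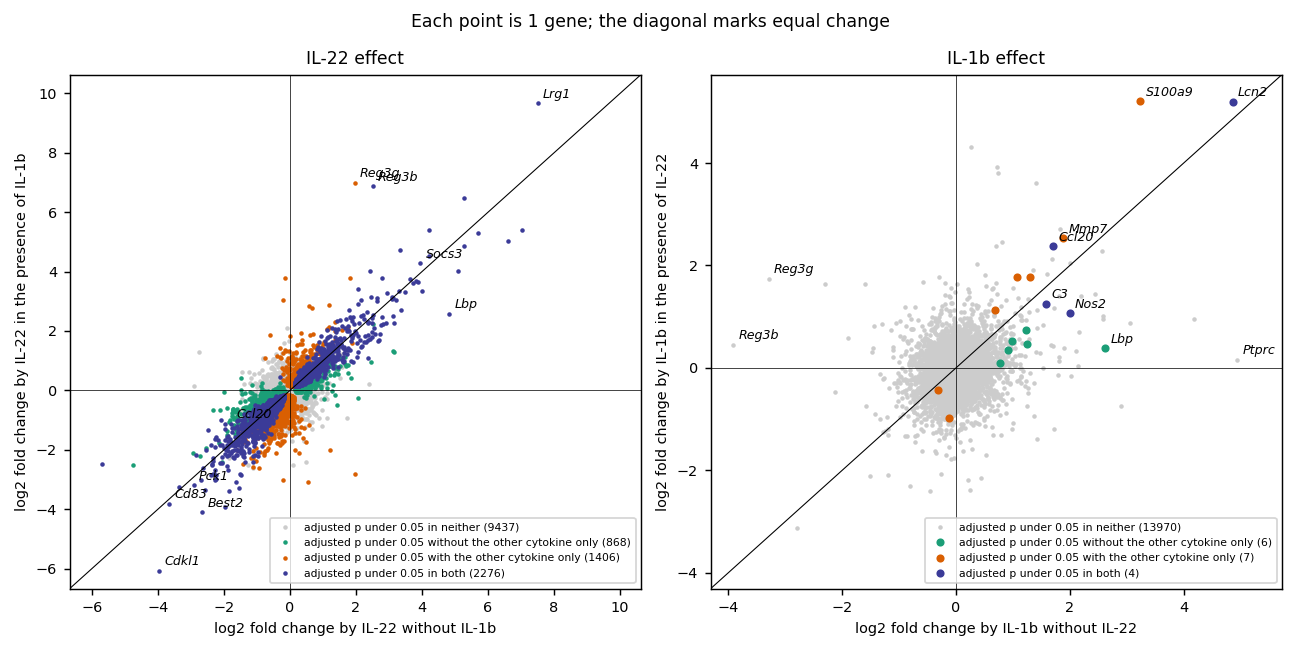
Log2 fold change of each tested gene by IL-22 without (x axis) and in the presence of IL-1b (y axis) on the left, and by IL-1b without and in the presence of IL-22 on the right; colours mark genes with an adjusted p under 0.05 in neither, either or both comparisons, and the diagonal marks equal change. IL-22 effects lay along the diagonal (r = 0.80), and few genes left the cloud around 0 for IL-1b.

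Receptor and remaining list results were as follows. Il22ra1, the IL-22 receptor subunit gene, stood at 143 ± 5.71 CPM in unstimulated cultures and did not pass the test in any comparison. Neither did the polymeric immunoglobulin receptor gene Pigr (0.01 ± 0.05 with IL-22 against unstimulated). Counts of abundant genes levelled off, so values near 0 in such genes may hide a change. With the trend on count per exon base removed Pigr passed as lower with IL-22 (-0.14, adjusted p = 0.0148), with both against unstimulated (-0.11, adjusted p = 0.0426) and with both against IL-1b (-0.13, adjusted p = 0.0170). Il1r1 stood at 13.0 ± 3.48 CPM in unstimulated, 8.23 ± 4.69 with IL-22 and 5.96 ± 1.65 with both. It did not pass the test with IL-22 alone, except without IL-22 replicate 1 (-1.24, adjusted p = 0.00800). Of 11 IL-22 receptor pathway genes, 2 rose with IL-22 and 1 fell, also adjusted over the list alone (camera, higher, adjusted p = 0.00834, and 0.432 with an estimated correlation). Those that rose were Stat3 and Socs3, which are also in the STAT3 list, and 4 of the 11 stood above 0. The median of the receptor list was -0.03 and its mean 0.36. With both cytokines against IL-1b alone that receptor list had 3 higher, and 3 and 1 lower adjusted over the list alone. Those higher were Stat3, Socs3 and Socs1, which are in the STAT3 list too. The camera adjusted p was 0.00221, and 0.397 with an estimated correlation, with a median of -0.01 and a mean of 0.45. Of 21 IL-1 receptor pathway genes, 10 rose and 3 fell with IL-22, also adjusted over the list alone (camera adjusted p = 0.0742, and 0.0281 without unstimulated replicate 1), among them Traf6 (0.42 ± 0.07). Camera with IL-22 against unstimulated made no call for interferon-stimulated (5 higher and 1 lower of 38, adjusted p = 0.432), antigen presentation (1 and 1 of 16, adjusted p = 0.941) and Paneth cell genes (1 and 1 of 5, adjusted p = 0.470). It made none either for enteroendocrine (2 higher of 22, adjusted p = 0.170), proliferation (4 higher of 36, adjusted p = 0.140) and tuft cell genes (1 higher and 1 lower of 6, adjusted p = 0.330). Adjusted over the list alone, proliferation had 1 higher and tuft cell genes 1 higher and 2 lower, and the other 4 lists had the same counts. For antigen presentation and stem cell genes the mean was below 0 while the median and the test were above it. The dissociation and heat-shock list had 9 higher and 1 lower of 17 with IL-22, also adjusted over the list alone (adjusted p = 0.00443, and 0.330 with an estimated correlation), with Dusp1 at 0.58 ± 0.09 and Egr1 at 0.52 ± 0.12. Of the lists for other cell types, fibroblast and smooth muscle genes had 1 of 6 lower with IL-22 (Pdgfrb, -0.89 ± 0.17; camera adjusted p = 0.657). Endothelial genes had 1 of 4 lower (Pecam1, -2.29 ± 0.44) and neural genes none of 2 called, and these lists were too small for camera. Counts for the 3 lists adjusted over the list alone were the same. Of 7 immune genes 2 rose with IL-22 and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0392, and 0.344 with an estimated correlation). These were Cd68 (1.76 ± 0.27), Cd14 (0.65 ± 0.09) and Kit (-1.07 ± 0.35). Kit lost its call without unstimulated replicate 1 (adjusted p = 0.106) or 2 (0.169) or IL-22 replicate 2 (0.127) or 3 (0.124) and with the trend removed (0.108), and the list's call was lost without unstimulated replicate 1 (adjusted p = 0.0863). Over all comparisons 138 list tests were made and 55 gave a camera call, of which 16 held with an estimated correlation. These were the antimicrobial list in 5 comparisons (all but the interaction) and the STAT3 and ER stress lists in the 3 that added IL-22. The others were the NF-kB list with IL-1b alone, with both against unstimulated and with both against IL-22, and the chemokine list with IL-1b alone and with both against IL-22.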

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

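The tests on Y-linked genes and on Xist were chosen only after the result was seen. Leukocyte transcripts were high in IL-1b replicate 1, with 104 Ptprc counts (20 and 12 in the other IL-1b libraries), 130 of Laptm5 (28 and 32) and 76 of Coro1a (14 and 9). The genes Folh1 and Prkd1 had 142 and 62 counts there and at most 1 elsewhere, and 51 of Cd4 and 68 of Il7r stood against at most 7 and 6, whereas Lyz2 and Tyrobp had none. Coro1a, Folh1, Prkd1, Cd4, Il7r, Lyz2, Tyrobp and Xist were chosen after their values were seen. A signal in genes that no comparison used drew attention to this library: 6 Y-linked genes summed to 58 counts there and to 0 in the other 11 libraries. RNA from a male source, such as leukocytes or another sample, may therefore have entered this library. The female transcript Xist stood at 0.915 of the median of the other 11, which argues against a library that was male throughout. IL-1b stimulation itself stays open for part of the pattern. Without this replicate the median of the 7 immune genes was 0.26, and camera kept its call at the preset correlation (adjusted p = 3.31e-05). With all libraries camera also called the list at that correlation, but not with an estimated one (adjusted p = 0.0855). The estimated correlation was not tried without this replicate.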

How the results depend on the processing

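The alternatives without the trend on count per exon base, with genes under 0.1 count per exon base, with position-corrected counts and with the pair of doubted libraries left out were chosen only after the data were seen. Among named genes 6052 results kept their direction and side of the threshold, 412 became weaker, 31 stronger and 3 reversed. The 3 were Pigr with the trend removed, at -0.14 with IL-22, -0.11 with both against unstimulated and -0.13 with both against IL-1b. Among list tests 1025 stayed, 61 became weaker and 18 stronger, and among counts 261 stayed within 1.5 times and 66 moved. Without a filter, 212 genes were called for IL-1b, 336 for both against IL-22 and 50 for the interaction, and with the DESeq2 Wald test 32, 87 and 4. Directions moved too: no filter gave 156 higher and 56 lower for IL-1b and 120 and 216 for both against IL-22, and DESeq2 22 and 10, and 27 and 60. Both against IL-22 gave 7 with a replicate block, 6 with only the 6 libraries compared and 5 with unstimulated replicate 1 and IL-1b replicate 1 left out. With genes under 0.1 count per exon base, 8700 genes were tested, and 1548 were called for IL-22, 5 for IL-1b, 2111 for both against unstimulated and 1932 for both against IL-1b, of which 1381, 5, 1857 and 1741 were also called among all genes. The overlap of IL-22 and IL-1b calls was 22 with DESeq2 (14 higher and 8 lower) and 5 at an adjusted p under 0.01, against 8 (all higher). Leaving out 1 library gave 1992 (without unstimulated replicate 2) to 3350 genes for IL-22, 9 to 28 (without unstimulated replicate 3) for IL-1b, 2648 to 3662 for both against unstimulated, 3 (without combined replicate 3) to 72 (without IL-22 replicate 1) for both against IL-22, 2567 to 3113 for both against IL-1b and 0 to 1 (without IL-1b replicate 1) for the interaction. The cause of these moves was not tested. Depth limits genes with few counts, such as Lcn2 and Lrg1 in unstimulated cultures.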

Other observations

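The gene family tests and the tests on counts at one position and on Lrg1 were chosen only after the result was seen. Of 42 tested cytochrome P450 genes (symbols beginning Cyp), 24 fell with both cytokines against unstimulated, against 13.7% of all genes (Fisher exact test, odds ratio 8.48, Benjamini-Hochberg adjusted p = 4.08e-08 over 808 tests of 202 symbol families), and 19 fell with IL-22 alone (adjusted p = 6.03e-06). They included Cyp1a1 (-2.77 ± 0.46 with both), the steroid side-chain enzyme gene Cyp11a1 (-2.09 ± 0.25), the sterol hydroxylase gene Cyp27a1 (-1.94 ± 0.21) and Cyp2c40 (-1.72 ± 0.16), chosen after their values were seen. Carboxylesterase genes fell in 8 of 12 cases with both (adjusted p = 0.00331) and 7 of 12 with IL-22 (0.00664), with Ces1c at -2.12 ± 0.35, Ces1g at -1.89 ± 0.34 and Ces2g at -1.18 ± 0.09. Solute carrier genes fell in 58 of 238 cases and rose in 34 with both (adjusted p = 0.00124), among them the neutral amino acid transporter gene Slc6a19 (-2.09 ± 0.33) and the serotonin transporter gene Slc6a4 (-1.15 ± 0.21). Proteasome regulatory subunit genes rose in 9 of 14 cases with both (adjusted p = 0.00253), such as Psmd14 (0.31 ± 0.06), and annexin genes in 7 of 12 (0.0366), such as Anxa5 (0.54 ± 0.10). With the trend on count per exon base removed, the lower counts were 24 Cyp, 11 Ces and 67 Slc genes, with adjusted p of 1.92e-08, 4.90e-07 and 3.30e-07, and the higher ones were 6 Psmd and 5 Anxa genes, which no longer passed (adjusted p = 0.266 and 0.367). Genes beginning Ugt had not passed with both (7 of 16 lower, adjusted p = 0.135) and did with the trend removed (4.17e-06). So did Ugt and Slc genes, as lower, with IL-22 alone (3.02e-06 and 0.00905). With the trend left in, 11 family tests were called in all, the other 4 for symbols beginning Mir, of which 1 of 123 changed in each direction in each comparison. Cyp2c and Ces1 genes are close paralogs, and any reads shared between them could have been split in counting, so the count per member is uncertain. The Fisher test treats members of a family as independent, so its p-values are too small where members vary together.

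Fold changes followed the count per exon base in the comparisons with IL-22. Counts of dense genes levelled off: genes at 0.4 or more counts per base followed those under 0.05 with a log-log slope of 0.277 (SE 0.124) over the 6 libraries without IL-22, where proportional counting gives 1. Whether counting reads at one position once is behind the trend stays open. A correction of counts for this left 0.991 of the difference between dense and sparse genes (median log2 fold changes of 0.13 and -0.17 with IL-22, against 0.13 and -0.18). It also left the levelling-off (slope 0.373, SE 0.173), so it does not decide. In simulated data with reads counted once and an assumed drop in depth the medians were 0.03 and -0.01. The simulation used the same model of positions as the correction, so it does not decide either. The libraries with IL-22 held 7.84% fewer counts, and the tables argue against depth as the whole cause: it predicted 0.0854 (SE 0.119) of the difference in trend. Why the trend differed between libraries with and without IL-22 stays open, and a change in RNA composition with IL-22 was not tested.

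Unstimulated replicate 1 held 109 Reg3b and 42 Reg3g counts. Carry-over from an IL-22 library would have brought 106 Lrg1 counts, and 2 were seen, a ratio of 0.0189 with an upper counting limit of 7.22 counts, which argues against it. IL-22-like signalling in that culture would raise the other IL-22 genes. The 250 genes raised at least 2-fold by IL-22 had a median log2 ratio of 0.01 (0.00916) in that library over the other unstimulated ones (bootstrap -0.02 to 0.07). Those genes were picked with that library among the controls, which favours genes not raised in it. The test thus leans towards no rise and does not settle the point. A few cells with high Reg3 expression may also be a source, which was not tested.

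For each comparison of 6 libraries only 10 splits exist, too few for a share under 0.05. Counting the real one, 1 of 10 splits gave as many genes in each. The real counts and the highest of the other splits were 3144 and 0 for IL-22, 10 and 0 for IL-1b, 3783 and 0 for both against unstimulated, 11 and 2 for both against IL-22, and 3682 and 0 for both against IL-1b. For the interaction, no gene was called, so any split reaches that count (100 of 100 drawn, highest other count 0) and these splits decide nothing.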
